A study of Homo sapiens with 12 samples.

How the data were processed

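RNA sequencing was analysed from 12 libraries of HepG2, an established human hepatoma cell line, with 3 libraries in each of 4 groups. Per the labels, one cell line stably expresses control shRNAs (CTL) and the other shRNAs against the transcripts of both macroH2A genes (double knock-down, DKD). The shRNA cassettes were integrated by retroviral transduction. Each line was left untreated, with the vehicle alone, or received 20 ng/mL of TNFα for 24 hours after a night in medium with little serum. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. They also do not say whether each arm was one pool of transduced cells, so differences between the lines cannot be told from effects of the knock-down.

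The authors deposited a table of estimated counts per gene symbol, which are whole numbers as deposited. Per the submitters' processing notes, CASAVA 1.7, Salmon 0.14.0 and DESeq2 were used with the human genome GRCh38/hg38. Salmon assigns reads to transcripts, and the step from transcripts to genes, the annotation and the strand setting are not given in the sources used here. A second deposited table holds a normalised signal. In each library it equals the counts divided by one size factor, with a relative spread of the ratio of at most 1.021e-14, so it adds no independent measurement. All 12 columns were matched to samples by their titles.

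The table lists 35984 genes, of which 10456 had no count in any library. Library totals ran from 30955080 counts (CTL untreated, replicate 2) to 42094144 (DKD untreated, replicate 2). One count was worth 0.0238 to 0.0320 CPM (counts scaled to the library total), which sets the floor of what can be seen. CPM was computed here from these counts with TMM factors. Mitochondrially encoded genes took 7.59% to 10.3% of the counts, and the 10 most abundant genes 8.74% to 11.3%. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 12.2 to 141.

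Tests were run with edgeR 4.0.16 in R 4.3.3 on the estimated counts. The model had 1 mean for each of the 4 groups and used all 12 libraries, so that the groups shared one estimate of the spread with 8 residual degrees of freedom. The spread was not equal, however. Chi-square per degree of freedom between replicates reached 141 in untreated and 80.8 in TNFα-treated knock-down cells, against at most 37.9 in control cells. Numbers of genes called in the 2 lines are therefore not directly comparable. TMM factors, the filter filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test were used, which left 16118 genes. Unless stated otherwise, each adjusted p is from this test, with Benjamini-Hochberg adjustment over the 16118 genes, and a gene was called at an adjusted p under 0.05. Fold changes are log2 values with standard errors (SE). The 5 contrasts were TNFα in control cells, TNFα in knock-down cells, knock-down without TNFα, knock-down with TNFα, and the interaction, which is the TNFα effect in knock-down cells minus that in control cells. Contrasts averaged over both cell lines or both treatments came from the same model.

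The size of the TNFα response was compared over genes called for the TNFα effect averaged over both lines, since choosing genes in one line favours that line. It was given as the median interaction, the share of genes with a smaller response in knock-down cells, and a total least squares slope, with fry (limma 3.58.1) as the test. The 17 gene lists were NF-kB feedback and signalling, chemokines and cytokines, interferon-stimulated genes, MHC class I antigen presentation, acute-phase proteins and complement, hepatocyte secreted proteins, hepatic transporters with bile acid and drug metabolism, liver transcription factors, cholesterol biosynthesis and uptake, cell cycle, p53 targets, unfolded protein and integrated stress response, extracellular matrix and mesenchymal genes, hypoxia and glycolysis, histone H2A variants and linker histones, markers of other cell types, and mitochondrially encoded genes. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. The lists, the contrasts, the design and the rule for named genes were fixed before the data were examined. A few list members that met this rule are not reported here, and they remain in the list tests and counts.

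The rule for named genes takes MACROH2A1 and MACROH2A2 in every comparison. For each contrast it takes up to 8 called genes with the largest rise and 8 with the largest fall (5 and 5 for the interaction). These need an average log2 CPM of at least 2, groups that do not overlap (not asked of the interaction) and a symbol that is not a clone or locus name. From each list it adds up to 4 called members with the smallest p. Genes outside the rule are marked where they appear. Positions are from GENCODE v29 on GRCh38, in which 15985 of the 16118 tested genes and all 107 named genes were found by symbol.

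The labels number the libraries 1 to 3 in every group. Whether the numbers pair libraries was checked on deviations from the group means. All 18 correlations between libraries of the same number lay above 0.1, from 0.193 to 0.695. Those between different numbers ran from -0.544 to 0.311, with a median of -0.286. All values below 0 joined replicate 1 with replicate 2 or 3. Between replicates 2 and 3 they ran from 0.0388 to 0.311, overlapping the values of equal number. The separation was therefore clearest for replicate 1. Still, 12 of 12 libraries had their closest library of another group under the same number. The pairing therefore comes from the data, and the fit with the replicate number as a block (6 residual degrees of freedom) is given beside the main results whose call or count it changes, though not beside every one. Blocking lowered the common dispersion from 0.0460 to 0.0120.

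Alternatives set in advance were median-ratio factors, library size alone, DESeq2 1.42.0, limma-voom, limma-trend on log2 of the normalised table plus 1, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), only the 2 groups compared, the block, a threshold of 0.01, a test against a fold of 1.5, and leaving out each library in turn. Added after seeing the data were fits on replicates 2 and 3 only, DESeq2 and limma-voom with the block, and counts outside 3 chromosome segments. These segments are runs of expressed genes whose running median over 25 genes differed between the lines by at least 0.3 on the log2 scale, joined across gaps of up to 10 Mb. The method and its thresholds were chosen after a regional shift had been noticed.

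The steps were tested on simulated counts for the 16118 genes with the observed means and library sizes. Changes were given only to genes with an average log2 CPM of at least 2, so recovery among lower genes was not tested. The simulated spread came from the fit with the block, and each replicate number shifted all groups alike. In the data without TNFα, replicate 1 deviated at least 2-fold from replicates 2 and 3 in 2550 genes of knock-down cells and 914 of control cells. Recovery and false calls in these libraries may therefore be worse than the simulated values. In the simulated TNFα contrast in control cells, the test without the block recovered 37.3% of genes changed 1.5-fold, 74.6% changed 2-fold and 97.0% changed 4-fold, with 0 false calls among 15718 unchanged genes. With the block these were 65.7%, 100% and 100%, with 22 false calls. For the interaction they were 8.96%, 32.8% and 92.4% without the block (0 false calls) and 44.8%, 91.0% and 100% with it (14 false calls). Genes simulated with a slope of 0.5 gave slopes of 0.549 and 0.536. All of them rose in simulated control cells by more than 0.64, the median of the real genes that rose. Weaker responses were not covered. Reads shared by near-identical genes cannot be assigned with certainty, which applies to the HLA genes, CYP3A5, the CSAG and MAGEA families and TBC1D3. Figures were drawn with matplotlib 3.10.9.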

Results

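Transcripts were measured by RNA sequencing in HepG2 hepatoma cells carrying control shRNAs or shRNAs against macroH2A1 and macroH2A2, histone H2A variants with a large C-terminal domain. Cells were untreated or given TNFα, an inflammatory cytokine, at 20 ng/mL for 24 hours, with 3 libraries per group. Depth was lowest in CTL untreated replicate 2, at 30955080 estimated counts, and ran from 37780825 to 42094144 in the other libraries. The series title places the study in the inflammatory response of cancer cells. The comparisons therefore asked what TNFα changed in each line, how the lines differed, and whether the response itself differed. In a principal component analysis, the replicate 1 libraries of the knock-down stood apart on the first component (33.0% of the variance), at -83.7 without TNFα and -53.9 with it, while the other 10 libraries lay between -18.2 and 41.5.

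Both target transcripts were low in all 6 knock-down libraries. MACROH2A1 (chromosome 5, 135333900 to 135399914, minus strand) fell from 236 ± 27.4 to 46.2 ± 12.2 CPM without TNFα (SD, n = 3), a log2 fold change of -2.35 (SE 0.20, adjusted p = 8.74e-05). With TNFα it stood at 268 ± 11.04 in control and 55.5 ± 10.1 CPM in knock-down cells (log2 fold change -2.27, SE 0.20). MACROH2A2 (chromosome 10, 70052796 to 70112280, plus strand) fell from 57.8 ± 2.85 to 5.11 ± 0.79 CPM without TNFα (log2 fold change -3.50, SE 0.16, adjusted p = 1.16e-06). With TNFα the fold change was -3.55 (SE 0.16). The remaining MACROH2A1 was 19.5% and 20.7% of control without and with TNFα, and the remaining MACROH2A2 8.83% and 8.55%. Neither gene passed the test for TNFα in control cells (adjusted p = 0.787 and 0.350, and 0.301 and 0.0929 with the block), although with TNFα MACROH2A1 was higher and MACROH2A2 lower in all 3 pairs of equal number in each line.

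**Figure D1:**
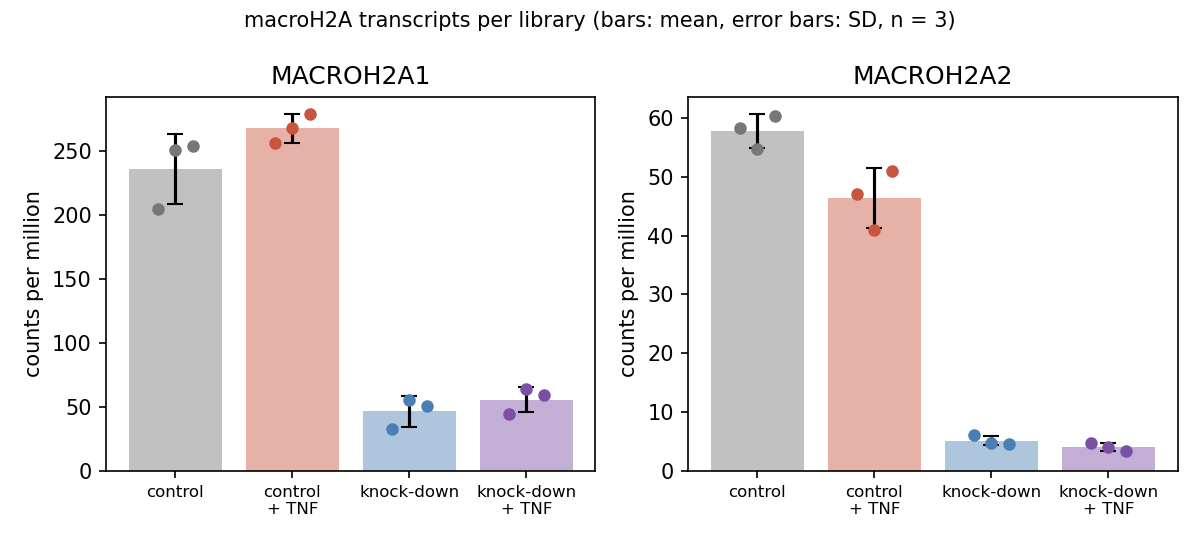
CPM of MACROH2A1 (left) and MACROH2A2 (right) in each library (points), with the mean (bar) and SD (error bar) of 3 libraries per group. Knock-down cells averaged 46.2 and 55.5 CPM of MACROH2A1 without and with TNFα, against 236 and 268 in control cells.

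In control cells, TNFα raised targets of NF-kB, the transcription factor it activates, and antigen-processing genes, and lowered several hepatocyte genes. UBD (FAT10, a ubiquitin-like protein, chromosome 6, 29555515 to 29559925) rose from 3.43 ± 1.55 to 225 ± 36.7 CPM (log2 fold change 6.05, SE 0.46, adjusted p = 1.04e-04). BIRC3, an inhibitor of apoptosis, rose by 3.92 (SE 0.22), the NF-kB subunit gene RELB by 3.30 (SE 0.22), and the urokinase gene PLAU by 2.94 (SE 0.39) on the log2 scale. SERPINA3 (2.78, SE 0.51), the chemokine gene CCL20 (2.58, SE 0.55), CTHRC1 (2.50, SE 0.52) and the autophagy receptor gene OPTN (2.49, SE 0.16) also rose. Among genes that fell were DKK4, a Wnt antagonist (log2 fold change -2.36, SE 0.26), the fatty acid hydroxylase CYP4F3 (-1.96, SE 0.35), and NR1H4, the bile acid receptor FXR (-1.87, SE 0.23). RASA4 (-1.71), the manganese exporter SLC30A10 (-1.59), PTGDR2 (-1.53) and ZNF385B (-1.53) fell too. In all, 306 genes were called higher and 117 lower, or 1279 and 758 with the replicate block. From replicates 2 and 3 alone the counts were 1271 and 954. Leaving out one library moved the total called from 423 to between 149 (without CTL untreated replicate 3) and 709 (without DKD untreated replicate 1), and with only the 2 groups compared it was 662.

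By list, 15 of 33 measured NF-kB genes rose in control cells (25 adjusted over the list alone, 23 with the block) and none fell, including the inhibitor gene NFKBIA (log2 fold change 2.21, SE 0.17) and NFKB2 (2.31, SE 0.19). Camera gave this list an adjusted p of 3.71e-59, and adjusted p = 8.13e-04 with an estimated correlation. In MHC class I antigen presentation 8 of 18 members rose (12 adjusted over the list alone, 13 with the block), among them TAPBP (1.55, SE 0.08), TAP1 (1.02, SE 0.08), ERAP1 (0.71) and ERAP2 (0.86), with adjusted p = 0.00343 with an estimated correlation. Of 40 interferon-stimulated genes 6 rose (13 adjusted over the list alone, 17 with the block), including IRF1 (1.08), ISG20 (1.91), OAS1 (1.03) and GBP3 (1.60), with adjusted p = 0.00343 with an estimated correlation. Of 21 chemokine and cytokine genes 5 rose (10 adjusted over the list alone, 11 with the block), such as IL32 (2.15, SE 0.33) and CSF1 (1.75, SE 0.31). TNF itself was at 0.0267 ± 0.0244 CPM untreated and 4.24 ± 2.50 with TNFα, and LTB at 0.0668 ± 0.0544 and 2.43 ± 0.491. The chemokine list had adjusted p = 0.0759 with an estimated correlation, and 0.00621 with the block added.

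Of 33 hepatocyte secreted proteins 5 fell with TNFα in control cells (13 adjusted over the list alone, 15 with the block). RBP4 fell (log2 fold change -1.07, SE 0.11), as did the fetal plasma protein gene AFP (-0.94, SE 0.11), TF, which encodes transferrin (-0.84, SE 0.14), and APOA1 (-0.57, SE 0.08). This list had adjusted p = 0.0106 with an estimated correlation. Acute-phase and complement genes went both ways. C3 (1.07, SE 0.12) and SERPINA3 rose, HP (haptoglobin, -1.37, SE 0.15) and the fibrinogen gene FGG (-1.59, SE 0.23) were among 3 that fell (block: 4 higher, 8 lower), and the list had adjusted p = 0.263 with an estimated correlation. In drug and bile acid metabolism CYP3A5 (1.42) and NR0B2 (0.71) rose and NR1H4 fell. Among liver transcription factors GATA6 rose (1.42) and FOXA1 fell (-0.65). The cholesterol and cell cycle lists lay lower with camera, with adjusted p = 0.263 and 0.286 with an estimated correlation, and CDC25C (-0.61) was the only cell cycle gene called lower (block: 13 and 5 lower in the 2 lists). The matrix genes FN1 (1.13), ITGA2 (1.46) and LAMC1 (0.46) rose and LOX fell (-1.37). The matrix list passed camera at adjusted p = 0.0168, but not with the block (0.118) or an estimated correlation (adjusted p = 0.174 with an estimated correlation). The serine synthesis genes PHGDH (-0.70) and PSAT1 (-0.50) and the p53 target TRIAP1 (-0.39) fell. LYZ, the only called marker of other cell types, rose by 1.40 and is abundant in these cells at 382 ± 26.8 CPM untreated. No hypoxia, histone or mitochondrially encoded gene was called without the block.

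In knock-down cells, TNFα raised many of these genes too and lowered hepatocyte genes. UBD rose from 10.3 ± 4.91 to 301 ± 56.4 CPM (log2 fold change 4.87, SE 0.43, adjusted p = 3.00e-04). BIRC3 (3.54, SE 0.21), PLAU (3.39, SE 0.41), RELB (2.79, SE 0.22), CCL20 (2.46, SE 0.54), the transglutaminase gene TGM2 (2.38, SE 0.22), CTSS, which encodes cathepsin S (2.34, SE 0.28), and NFKBIA (2.20, SE 0.17) rose. FGA (-2.34, SE 0.43), FGB (-2.29, SE 0.22), FGG (-1.61, SE 0.23) and the albumin gene ALB (-1.29, SE 0.23) fell. In control cells FGB fell too (-1.155, adjusted p = 0.0193), and FGA (-1.75, adjusted p = 0.0571) and ALB (-0.92, adjusted p = 0.0644) passed with the block (0.00352 and 6.50e-05). HNMT (-1.08), SEMA3A (-1.07), AFP (-0.95, SE 0.11) and PEG10 (-0.85) fell as well. Called genes numbered 248 higher and 41 lower, or 894 and 343 with the block and 913 and 447 from replicates 2 and 3 alone. The total of 289 ranged from 127 (without DKD TNFα replicate 3) to 357 (without DKD untreated replicate 1) when one library was left out, and was 36 with only the 2 groups compared.

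The lists in knock-down cells showed 15 of 33 NF-kB genes higher (23 adjusted over the list alone, 24 with the block), TNIP1 (1.31, SE 0.11) among them, with adjusted p = 8.06e-04 with an estimated correlation. Of 18 MHC class I genes 9 rose (13 adjusted over the list alone, 12 with the block), led by TAPBP (1.63, SE 0.08) and ERAP2 (1.12, SE 0.11), with adjusted p = 0.00157 with an estimated correlation. Of 40 interferon-stimulated genes 6 rose (14 adjusted over the list alone, 16 with the block), among them IRF1 (1.17), ISG20 (1.56), OAS1 (1.03) and GBP3 (1.72). Of 21 chemokine genes 6 rose (10 adjusted over the list alone, 9 with the block), including IL32 (1.65), CSF1 (1.46) and CX3CL1 (0.86). That list had adjusted p = 0.118 with an estimated correlation, and 0.0218 with the block added. Of the hepatocyte secreted proteins 5 fell (9 adjusted over the list alone, 10 with the block), among them RBP4 (-0.79) and APOA1 (-0.44), with adjusted p = 0.0108 with an estimated correlation. In the acute-phase list C3 was 1 of 2 that rose (1.04), and 4 fell (7 with the block). Its adjusted p = 0.144 with an estimated correlation. The cholesterol, cell cycle, matrix and mitochondrial lists passed camera but had adjusted p = 0.429, 0.669, 0.178 and 0.613 with an estimated correlation. The matrix list was also lost with the block (0.320). CYP3A5 (1.62), GATA6 (1.60), FN1 (1.16), ITGA2 (0.89), LAMC1 (0.47) and LYZ (1.28) rose. The p53, stress response, hypoxia and histone lists had no called member without the block.

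The calls in the 2 lines overlapped far more than independent lists would, although these set a low mark, since both comparisons share one spread per gene. Without the block, 191 genes rose in both lines against 4.71 for independent lists, and 26 fell in both against 0.298, with none called in opposite directions. With the block 743 rose in both and 263 fell in both, against 70.9 and 16.1, and 1 gene was called in opposite directions. The TNFα fold changes of the lines correlated across all 16118 genes (Pearson r = 0.545, Spearman rho = 0.594), and genes are not independent replicates.

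**Figure D2:**
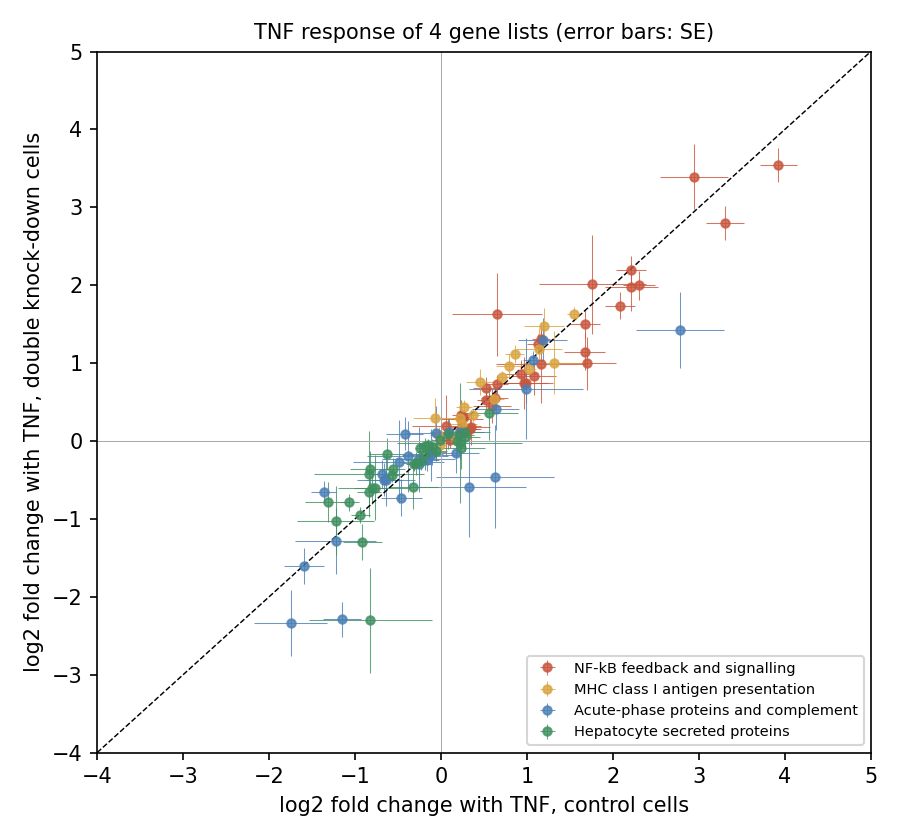
Log2 fold change with TNFα in control cells (x axis) and in double knock-down cells (y axis) for members of 4 lists, with SE as error bars and equal responses as a dashed line. BIRC3 lies farthest right, at 3.92 in control and 3.54 in knock-down cells, and FGB at -2.29 in knock-down cells.

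Without TNFα, knock-down cells held more transcripts of liver plasma proteins than control cells. ALB (chromosome 4, 73397114 to 73421412) was at 6243 ± 1956 CPM against 473 ± 79.9 (log2 fold change 3.72, SE 0.25, adjusted p = 2.13e-05), and FGB at 458 ± 114 against 53.3 ± 12.5 (3.10, SE 0.23). LTBP1, a TGF-beta binding protein gene, was higher by 4.40 (SE 0.24), GNG12 by 3.98 (SE 0.23), the adhesion gene ALCAM by 3.59 (SE 0.24), SLC6A14 by 3.19 (SE 0.45), SEZ6L2 by 3.14 (SE 0.36) and the phosphatase gene PTPRJ by 3.05 (SE 0.14). Genes that were lower included TTN (log2 fold change -4.80, SE 0.37), GRAMD1A (-3.74, SE 0.48), PPP1R3B, a glycogen-targeting phosphatase subunit (-3.04, SE 0.24), and PODXL (-2.83, SE 0.39). KCNIP4 (-2.58), SERPINE2 (-2.43) and CDH16 (-2.42) were also lower. Called genes numbered 504 higher and 299 lower, or 1478 and 1179 with the block and 1155 and 828 from replicates 2 and 3 alone. The total of 803 ranged from 423 (without CTL untreated replicate 3) to 917 (without DKD untreated replicate 1) with one library left out, and was 321 with only the 2 groups compared.

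In the acute-phase list 9 of 28 members were higher in untreated knock-down cells (14 adjusted over the list alone, 17 with the block) and none lower. FGG (log2 fold change 2.42, SE 0.24), FGA (2.81, SE 0.44) and HP (0.98, SE 0.14) were among them, with adjusted p = 0.0155 with an estimated correlation. Of 33 hepatocyte secreted proteins 7 were higher (9 adjusted over the list alone, 18 with the block), including PROC (0.53), TTR (0.52) and SERPINC1, which encodes antithrombin (1.36, SE 0.26). That list had adjusted p = 0.0369 with an estimated correlation, and 0.0674 with the block added. In the replicate 1 library of this group, the median acute-phase gene stood 0.51 above replicates 2 and 3 on the log2 scale and the median secreted protein 0.27. Among bile acid, drug and transport genes 4 were higher and 1 lower (8 and 1 adjusted over the list alone, 16 and 1 with the block). AKR1B10 (1.60), NR1H4 (1.62), CYP27A1 (0.64) and ABCC3 (1.43) were the 4, with adjusted p = 0.192 with an estimated correlation and 0.0172 with the block added. The matrix genes TIMP3 (2.93, SE 0.25), SPARC (1.64, SE 0.19), LOX (1.75, SE 0.22) and FN1 (0.37) were higher (block: 7 higher, 6 lower), with adjusted p = 0.294 with an estimated correlation.

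Inflammatory lists did not stand apart between the untreated lines with camera, while fry gave interferon-stimulated genes an adjusted p of 0.0287 toward higher values (0.0524 with the block). PLAU (log2 fold change -2.40, SE 0.40) and NFKB1 (-0.52) were lower and CFLAR higher (0.61). The death ligand gene TNFSF10 was higher (1.96), from 0.974 ± 0.381 to 3.83 ± 0.575 CPM. IFIH1 (1.33) and PARP9 (0.41) were higher and SAMD9 lower (-2.12) (block: 10 higher, 4 lower among 40 interferon-stimulated genes). The peptidase genes ERAP2 (-0.87) and ERAP1 (-0.38) were lower. The proliferation marker MKI67 (-0.73), UBE2C (-0.98), HYOU1 (-0.27) and BNIP3 (-0.46) were lower, and SPATA18 (0.66) and VLDLR (1.28) higher. CD4, a T-cell marker, was lower (-1.92) at no more than 1.31 CPM in any group mean. The cell cycle list passed camera toward lower values (adjusted p = 0.0275), with adjusted p = 0.860 with an estimated correlation, and its median member in DKD untreated replicate 1 stood at -0.889 relative to replicates 2 and 3 on the log2 scale. Without that library its direction turned (adjusted p = 0.574). Liver transcription factors, histone genes and mitochondrially encoded genes had no called member without the block.

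With TNFα present, the same kinds of gene differed between the lines. LTBP1 (log2 fold change 4.31, SE 0.24), GNG12 (4.16, SE 0.22), ALCAM (3.75, SE 0.25), ALB (3.35, SE 0.25), PTPRJ (3.27, SE 0.15), TIMP3 (3.26, SE 0.26), SLC6A14 (3.07, SE 0.44) and SLC30A10 (2.91, SE 0.33) were higher in knock-down cells. TTN (-4.54, SE 0.36), GRAMD1A (-3.09, SE 0.45), PPP1R3B (-2.88, SE 0.24), KCNIP4 (-2.78), SERPINE2 (-2.62), EFNB2 (-2.55, SE 0.16) and PODXL (-2.34) were lower. NR1H4 was higher by 2.62 (SE 0.23, adjusted p = 1.02e-04), at 36.3 ± 10.6 CPM against 5.89 ± 1.19. In all 635 genes were higher and 370 lower, or 1716 and 1417 with the block and 1384 and 991 from replicates 2 and 3 alone. The total of 1005 ranged from 572 (without CTL TNFα replicate 2) to 1545 (without DKD untreated replicate 1) when one library was left out. Between the 2 treatments 415 higher and 245 lower calls were shared, against 19.9 and 6.86 for independent lists. No library is common to both comparisons. Each gene has one spread in the fit, however, so independent lists set a low mark. With the block 1177 and 907 were shared, against 157 and 104, and 1 gene was called in opposite directions.

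Of the acute-phase list 10 members were higher with TNFα (16 adjusted over the list alone, 19 with the block), among them HP (1.69), FGG (2.40), FGB (1.97) and FGA (2.22), with adjusted p = 0.0273 with an estimated correlation. Of the hepatocyte secreted proteins 8 were higher (15 adjusted over the list alone, 18 with the block), including PROC (0.65), RBP4 (0.79) and SERPINC1 (1.90). Their adjusted p = 0.0273 with an estimated correlation, and 0.0557 with the block added. In DKD TNFα replicate 1, the median acute-phase gene stood 0.41 above replicates 2 and 3 on the log2 scale and the median secreted protein 0.31. In transport and drug metabolism 9 were higher and 2 lower (11 and 2 adjusted over the list alone, 15 and 3 with the block), with CYP27A1 (0.95) and AKR1B10 (1.73) higher and CYP2B6 (-2.30) lower. That list had adjusted p = 0.248 with an estimated correlation, and 0.0317 with the block added. The p53 list passed camera toward higher values (2 called, SPATA18 at 0.97 and CCNG1 at 0.65), with adjusted p = 0.825 with an estimated correlation. With the block 8 of its members were called higher and 2 lower. LOX (2.24) and SPARC (1.82) were higher and ITGA2 lower (-1.005). CFLAR (0.60), TNFSF10 (2.64), IFIH1 (1.16), RXRA (0.66), CDC25C (0.46), VLDLR (1.42), PHGDH (0.69) and ACTA2 (0.65) were higher. PLAU (-1.95), CCL15 (-0.31), SAMD9 (-1.79), ERAP2 (-0.61), DNAJB11 (-0.53), HYOU1 (-0.31), BNIP3 (-0.45), the hexokinase gene HK2 (-0.57) and CD4 (-1.72) were lower. Fry gave interferon-stimulated genes an adjusted p of 0.0380 toward higher values, and camera did not pass them. LTB stood at 0.690 ± 0.397 CPM against 2.43 ± 0.491, and NLRC5 at 0.236 ± 0.0507 against 0.607 ± 0.257. Histone and mitochondrially encoded genes had no called member without the block.

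Part of the difference between the lines followed chromosome position. Genes on chromosome 2 from 95165432 to 241817413 were higher in knock-down cells by a median of 0.41 on the log2 scale, those on chromosome 9 from 14521 to 15465953 by 0.73, and those on chromosome 10 from 97640686 to 133421307 had a median of -0.53. In the 6 pairs of libraries with equal number and treatment these medians ran from 0.376 to 0.439, from 0.714 to 0.809 and from -0.540 to -0.509. The 3 segments hold 870 tested genes, 5.40% of all, and, without the block, 29.6% of the calls without TNFα and 26.7% with it. Outside them 337 genes were higher and 228 lower without TNFα, and 448 and 289 with it. With the block, 1146 higher and 1050 lower of 2657 calls lay outside without TNFα. With TNFα these were 1356 and 1282 of 3133. The segments thus held a smaller share of the calls with the block. CCL20, ZNF385B, FN1, HNMT, TTN, SERPINE2, CFLAR, IFIH1, PROC and CYP27A1 lie in the chromosome 2 segment, VLDLR in that on chromosome 9, and NFKB2, MKI67 and BNIP3 in that on chromosome 10. No member of the acute-phase list and 1 of the hepatocyte secreted list lie inside, and neither macroH2A gene does. Of the interferon-stimulated genes called higher without the block, 2 of 3 without TNFα and 2 of 2 with it lie inside. The median TNFα effect in control cells was near 0 in each segment, at -0.01, -0.06 and -0.01.

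**Figure D3:**
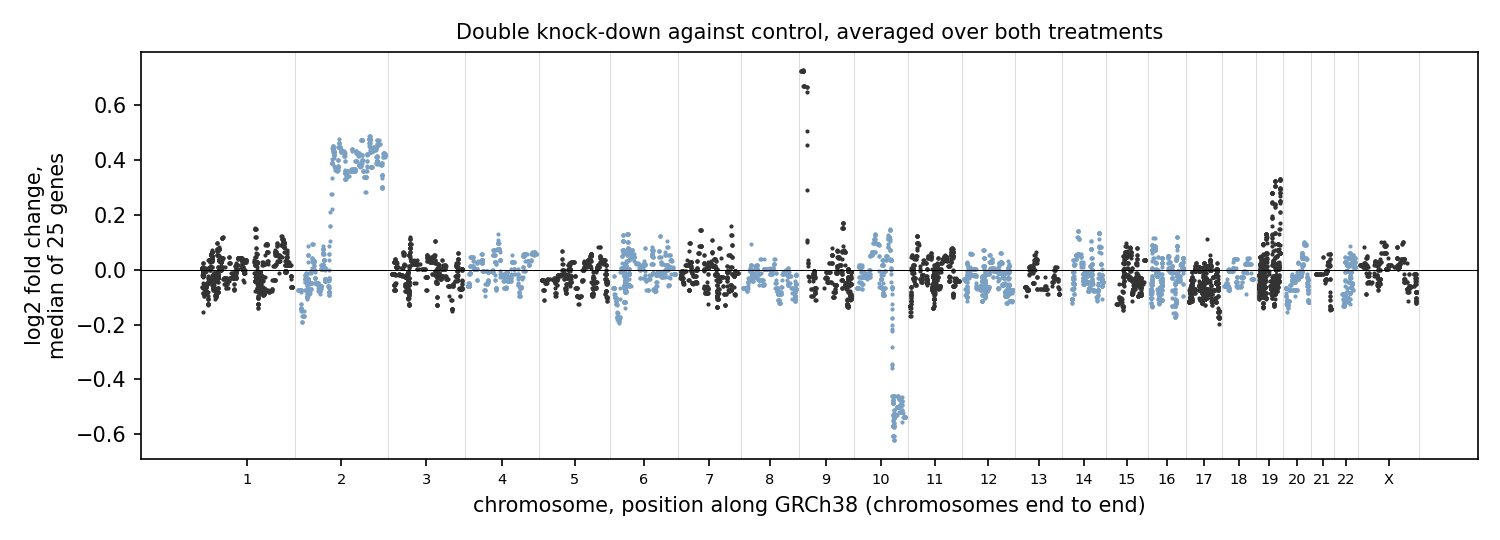
Running median over 25 genes of the log2 fold change between double knock-down and control cells, averaged over both treatments, along GRCh38 chromosomes laid end to end. Long runs lie apart from 0 on chromosomes 2 (median 0.41), 9 (0.73) and 10 (-0.53).

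Whether TNFα acted differently in the 2 lines was tested by the interaction. No gene was called by edgeR (smallest adjusted p = 0.821, and 0.394 with the block), and 184 genes had an unadjusted p under 0.05 (556 with the block), against 805.9 by chance. Counts below that number show that the test was conservative here, not that the responses were equal. In simulation it recovered 32.8% of 2-fold interactions without the block, among genes with an average log2 CPM of at least 2. The limma tools run also called 0. DESeq2 called 2 higher and 3 lower, namely CRYAA (interaction -1.75), ENSG00000259086, ENSG00000259784, RPL37P6 and TBC1D3D, and 9 and 13 with the block. The 22 include DKK4 (1.34), NR1H4 (0.99), OPTN (-0.54), TRPV2 (-0.90), FGB (-1.12) and UBD (-1.17). These genes were taken from that tool after its values were seen. By edgeR no adjusted p among them was below 0.821 without the block or 0.394 with it. In the list tests 3 passed camera: cell cycle genes (adjusted p = 5.56e-07), mitochondrially encoded genes (0.00207) and p53 targets (0.0482), all with adjusted p = 0.790 with an estimated correlation, and the chemokine list passed with the block (0.00259, against 0.206 without). Leaving out DKD untreated replicate 1 turned the direction of the cell cycle list (adjusted p = 0.488).

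As sets, genes that rose with TNFα did not pass a test for a different size in the 2 lines. Over the 809 genes that rose on average, the median log2 fold change was 0.64 in control and 0.59 in knock-down cells, with a median interaction of -0.04, and 58.7% had a smaller response in knock-down cells (adjusted p = 0.522 for the interaction by fry of limma, adjusted over the 2 sets, slope 0.97). In the 3 pairs of equal number the median difference between the lines over these genes was -0.0664, -0.0381 and -0.0177, so a small difference is not excluded. Over the 354 genes that fell, the medians were -0.48 and -0.37, with a median interaction of 0.10, and 75.4% fell by less in knock-down cells. For this set fry of limma gave adjusted p = 0.0590 over the 2 sets, and 0.0295 unadjusted. Over the same 354 genes in the fit with the block these were 0.0470 and 0.0235, and over the 1421 genes that fell in that fit 0.0330 and 0.0165. In the 3 pairs the median difference over the 354 genes was 0.148, 0.0763 and 0.0838. Over these genes the median interaction lay between 0.0670 and 0.117 with one library left out. The unadjusted fry value then reached 0.0626 and 0.0634 without CTL untreated replicates 1 and 3, 0.0695 and 0.0555 without CTL TNFα replicates 2 and 3, and 0.0516 without DKD TNFα replicate 1. Without all libraries of one number it was 0.0671 to 0.134 over these genes. When the genes were also chosen again without the library, the median was -0.014 and the fry value 0.981 without DKD untreated replicate 1, and the fry value 0.382 without DKD TNFα replicate 1. Without DKD untreated replicate 2, DKD untreated replicate 3 or CTL untreated replicate 3 it was 0.0742, 0.115 and 0.0613, and from replicates 2 and 3 alone 0.141 (0.137 with the block added). The slope over these genes, 1.84, moved between 0.766 and 4.10 with one library left out and the genes chosen again, and does not measure a size.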

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

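The tests chosen only after the result was seen were those on copy number, on differences between the stable lines, on control cells in replicate 1, on a condition shared by the libraries numbered 1, and on liver genes without replicate 1. 7 of 248 checks found all 3 pairs of libraries moving one way in one setting and all 3 the opposite way in the other. The genes checked had been chosen for their calls, so no number expected by chance is given. OPTN was higher in knock-down cells without TNFα and lower with it, a mean difference of -0.54 on the log2 scale. FOXA1 was lower without TNFα and higher with it (0.32). The lower side was small, from -0.108 to -0.0481 in the pairs for OPTN and from -0.174 to -0.0248 for FOXA1. The TNFα response of TNFSF10 was negative in control and positive in knock-down cells (0.71), as were those of CYP27A1 (0.31) and CCNG1 (0.20), and that of PARP9 was positive and then negative (-0.30). The positive side of these TNFα responses was small. In knock-down pairs it ran from 0.0546 to 0.208 for TNFSF10, 0.00200 to 0.271 for CYP27A1 and 0.00499 to 0.120 for CCNG1. In control pairs it ran from 0.00458 to 0.0606 for PARP9. The median level of the chemokine and cytokine list, taken in each library, differed by -0.99 between the knock-down effects with and without TNFα, while the median interaction of its 21 members in the fit was -0.16. The interaction test of edgeR called none of the 6 genes (adjusted p = 0.99997), with 0.394 for OPTN when the block was added.

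The 3 shifted segments and the genes of large change between the lines raise the question of how far the lines differ apart from the knock-down. When gene positions were permuted 1000 times, 10 permutations had a window median of 0.3 or more, up to 0.354, and 0 had a run of 25 genes, the least a segment needs. When runs were sought in every second expressed gene, they appeared on chromosomes 2 and 10 from either set of genes and on chromosome 9 from 1 of the 2. Of the genes between, which had no part in finding the runs, at least 94.2% shifted the same way when the runs of a chromosome were pooled, and 34 of 38 in the lowest single run. Of all tested genes in a segment at least 86.3% did, and of those too low to enter the windows 69.3%, 70.6% and 54.3% on chromosomes 2, 9 and 10, against 61.5%, 61.5% and 38.5% of such genes outside. A copy-number difference cannot be told apart from another regional difference here, since copy number was not measured and either shifts neighbours together. Of 478 genes of at least 2-fold change, 473 had 10 neighbours to read. The neighbours had a median shift of 0.0353 (interval 0.0233 to 0.0422). This argues against a copy-number difference of the surroundings for the typical gene of the set, but a median cannot speak for a minority. For 64 of the genes the neighbours shifted by over 0.3, and there it stays open. The test was redefined after a first result, to include neighbours that were themselves called. Other differences between the lines cannot be told apart from the knock-down, since each arm has its own line and the correlation of 0.674 across genes between the knock-down effects with and without TNFα (genes are not independent replicates) follows from either.

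Replicate 1 of the knock-down stood apart with and without TNFα. Of all libraries, DKD untreated replicate 1 had the highest share of mitochondrially encoded genes (10.3%) and of the 10 most abundant genes (11.3%). In DKD TNFα replicate 1 these were 8.97% and 10.2%. Whether RNA quality differed in these replicate 1 libraries was not tested. Control cells in those libraries, in the share that mixing alone would need, are argued against by genes all but absent from knock-down cells. The slopes of the knock-down effect in replicate 1 on that in replicates 2 and 3 were 0.603 and 0.760. They were taken over genes called in replicates 2 and 3, and this choice can lower such a slope without any mixing. Mixing alone would reach them with 30.4% and 16.9% of control cells, so the share needed may be smaller. The 4 genes abundant in control cells and at 5% or less of that in replicates 2 and 3 stood in replicate 1 at a median of 0.820% without TNFα and 1.14% with it, and at most 3.61%. A share this small stays open: in replicate 1 MACROH2A1 was at 15.8% of control without TNFα and 17.2% with it, below replicates 2 and 3, but MACROH2A2 was at 10.3% and 9.86%, above both. The criterion was changed 4 times after outcomes were seen: MACROH2A1 with the slope, MACROH2A1 alone, such genes at 1% or less (2 genes), and at least 5 genes at 5% or less came before, and the last asks for at least 3 genes. Of 28 markers of immune, endothelial, stromal and melanocytic cells 0 rose there, which argues against abundant cells of these kinds. Other kinds of cell had no markers in the list, so their presence was not tested. A condition shared by the libraries numbered 1 may account for part of it, since the deviation of replicate 1 correlated across genes between the lines (0.540 without TNFα, 0.505 with it; genes are not independent replicates).

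Liver secreted and acute-phase genes were higher in knock-down cells. Replicate 1 alone is argued against, since 28 of 61 members were called higher without TNFα from replicates 2 and 3 alone, and 31 with TNFα, against 16 and 18 from all libraries. Calls over all genes rose as well, from 803 to 1983 without TNFα and from 1005 to 2375 with it. The larger number of members is therefore no sign of a stronger difference. A few abundant genes shifting the scale are argued against by library size alone, which called 16 and 19 and moved the median of all genes by -0.00917 and 0.00146. The knock-down itself and other differences between the lines stay open, as untested.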

How the results depend on the processing

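Fits on replicates 2 and 3 alone, DESeq2 and limma-voom with the block, counts outside the segments, and the reading of the same TNFα genes in other fits were chosen only after the result was seen. Of 190 calls of named genes, all kept direction and side of the threshold with the replicate block, 189 with DESeq2, 183 with limma-voom, 148 with only the 2 groups compared, 133 at an adjusted p under 0.01 and 99, the fewest, for a fold above 1.5, and none reversed in any setting. Of 2280 such calls with one library left out, 1983 held. Of 85 list tests 82 held with the block, which ended the matrix list in both TNFα contrasts and brought in the chemokine list of the interaction; among calls of named genes and list tests at the preset correlation it changed no other. With an estimated correlation 66 held, and the calls that hold are NF-kB, interferon-stimulated, MHC class I and secreted protein genes for TNFα in both lines, and acute-phase and secreted protein genes for the knock-down with and without TNFα. With the block added as well, the secreted protein genes were lost for the knock-down (adjusted p = 0.0674 without TNFα and 0.0557 with it), and the other calls of this sort held. The lists past the threshold went from 9, 10, 5, 4 and 3 to 4, 4, 2, 2 and 0 over the 5 contrasts, and fry passed 5 for TNFα in knock-down cells and 0 for the interaction. Counts depend on depth and spread, and recovery of small changes was incomplete in simulation. Where a value moved, the cause was not tested.

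Genes higher and lower for TNFα in control cells (306 and 117) were 1279 and 758 with the replicate block, 660 and 410 with DESeq2, 129 and 31 at an adjusted p under 0.01, 61 and 6 for a fold above 1.5, 1271 and 954 from replicates 2 and 3, 2150 and 2038 from these with the block, 1466 and 1157 with DESeq2 and the block, and 1261 and 752 with limma-voom and the block. With only the 2 groups compared 203 were lower. In the same order, TNFα in knock-down cells (248 and 41) gave 894 and 343, 489 and 166, 115 and 14, 54 and 3, 913 and 447, 1786 and 1501, 1124 and 620, and 873 and 346, with 34 and 2 from only the 2 groups. Knock-down without TNFα (504 and 299) gave 1478 and 1179, 812 and 622, 229 and 143, 104 and 49, 1155 and 828, 2009 and 1694, 1606 and 1611, and 1480 and 1120, with 203 and 118 from only the 2 groups. Knock-down with TNFα (635 and 370) gave 1716 and 1417, 1028 and 732, 305 and 170, 124 and 51, 1384 and 991, 2232 and 1946, 1821 and 1700, and 1739 and 1357. Genes shared by the TNFα responses (191 and 26) gave 743 and 263, 383 and 122, 87 and 7, 41 and 1, 754 and 350, 1459 and 1167, 914 and 472, and 712 and 264, with 33 and 2 from only the 2 groups. For the interaction DESeq2 called 2 and 3, and 9 and 13 with the block.

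With one library left out, counts higher and lower ran from 115 to 482 and 34 to 227 for TNFα in control cells, 112 to 273 and 15 to 87 in knock-down cells, 255 to 581 and 168 to 336 for knock-down without TNFα, and 351 to 944 and 213 to 601 with it. Shared TNFα genes ran from 94 to 228 and 9 to 69, interaction calls lower from 0 to 1 (1 without CTL untreated replicate 2), and lists passed from 3 to 7 for knock-down without TNFα and 1 to 6 for the interaction. Totals moved by over 1.5 times for TNFα in control cells (423) without CTL untreated replicates 1, 2 and 3 (206, 213, 149), CTL TNFα replicates 2 and 3 (172, 193) and DKD untreated replicate 1 (709). For TNFα in knock-down cells (289) this held without CTL untreated replicate 3 (180), DKD untreated replicates 2 and 3 (149, 150) and DKD TNFα replicates 2 and 3 (150, 127). For knock-down without TNFα (803) it held without CTL untreated replicates 1, 2 and 3 (531, 471, 423) and DKD untreated replicate 2 (506), and with TNFα (1005) without CTL TNFα replicates 1, 2 and 3 (633, 572, 577) and DKD untreated replicate 1 (1545).

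In each setting the genes that rose or fell with TNFα were chosen again (354 fell without the block and 1421 with it), so a move holds a change of genes too, except where the same genes are named. Over genes that fell with TNFα, fry p for the interaction (0.0295) was 0.141 from replicates 2 and 3 and 0.137 with the block added, and 0.0124 to 0.981 with one library left out. Their median interaction (0.10) was 0.0591 with the block, 0.15 at an adjusted p under 0.01, 0.28 for a fold above 1.5, 0.0484 from replicates 2 and 3 with the block, 0.238 for genes chosen in control cells alone and -0.00944 for genes chosen in knock-down cells alone, and -0.0140 to 0.15 with one library left out. That of genes that rose (-0.04) was -0.099 and 0.063 by the same 2 choices, and -0.0879 to 0.0104 with one library left out, turning without DKD untreated replicate 1 (0.0104), DKD TNFα replicate 1 (0.00973) and DKD TNFα replicate 2 (0.00139). The slope over genes that fell (1.84) was 1.07 with the block, 0.787 with DESeq2, 1.09 with limma-trend, 3.21 at 0.01, -12.0 for a fold above 1.5, 1.096 from replicates 2 and 3, 0.973 with the block added, 4.40 with DESeq2 and the block, 0.944 with limma-voom and the block, 0.0358 and 9.84 for genes chosen in control and knock-down cells alone, and 0.766 to 4.10 with one library left out. Over genes that rose (0.972) it was 0.892 with limma-voom, 0.886 with limma-trend, 0.920 with the stricter filter, 0.893 with limma-voom and the block, 0.854 and 1.06 for genes chosen in control and knock-down cells alone, and 0.819 to 1.38 with one library left out. Over the same 354 genes, fry p for the interaction was 0.0235 with the block, 0.0897, 0.0781 and 0.134 without the libraries numbered 1, 2 and 3 (0.0671, 0.110 and 0.1296 with the block added), and 0.0228 to 0.0695 with one library left out. It passed 0.05 without CTL untreated replicates 1 and 3 (0.0626, 0.0634), CTL TNFα replicates 2 and 3 (0.0695, 0.0555) and DKD TNFα replicate 1 (0.0516). The median of the same 809 genes that rose was -0.0660 without CTL untreated replicate 2, -0.0706 without CTL TNFα replicate 1, -0.0764 without DKD TNFα replicate 3 and -0.00392 without DKD TNFα replicate 1, and below 0 in each case. The cell cycle list of the knock-down without TNFα turned from replicates 2 and 3 (adjusted p = 0.670, and 0.654 with the block) and without DKD untreated replicate 1 (0.574), with a range from 2.15e-05. That of the interaction turned without DKD untreated replicate 1 (0.488, from 2.10e-14), and the p53 list of the interaction without DKD untreated replicate 3 (0.974, from 3.48e-06).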

Other observations

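The tests on zinc-finger genes and the genes singled out here were chosen only after the result was seen. CCND2, which encodes cyclin D2 (chromosome 12, 4273772 to 4305350), was at 33.5 ± 2.47 CPM in untreated control cells and 30.97 ± 1.22 with TNFα (SD, n = 3), and the 3 knock-down libraries held 1 count in all without TNFα and 2 with it, against 3828 and 3826 in control cells. The cancer-testis genes MAGEA12 (log2 fold change -6.06 without and -6.27 with TNFα) and CSAG1 (-7.03 and -6.90), neighbours on the X chromosome, were also lower in knock-down cells, and their families share reads. X-linked genes as a set did not pass, with an adjusted p of 0.976 from camera with an estimated correlation.

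The 354 genes that fell with TNFα stood higher in knock-down cells on average over both treatments, with a median of 0.16 on the log2 scale, 255 of them positive, fry p = 6.02e-06 and camera p = 0.00840 with an estimated correlation. The choice of genes and this contrast are independent only with an equal spread. It was widest in untreated knock-down cells (chi-square per degree of freedom up to 141), where upward noise favours both. The p-values for these genes may therefore be too small. That liver genes of the fixed lists carry this alone is argued against by the 334 others, with fry p = 1.757e-05 and camera p = 0.0184 with an estimated correlation (0.0587 from replicates 2 and 3 alone). Few of the 354 genes were on these lists, and liver genes outside them were not removed. Whether liver genes as a whole carry the difference was therefore not tested. The 479 zinc-finger genes outside the segments had a median of 0.08 (0.0215 from replicates 2 and 3), and camera with an estimated correlation gave p = 0.323, so a shift of these genes as a set was not shown and is not excluded. The 238 on chromosome 19 had a median of 0.14 (0.0763 from replicates 2 and 3), with 56 called higher and 5 lower, and the 241 elsewhere 0.02 (-0.0102 from replicates 2 and 3), with 8 and 6. With the block these calls were 73 and 10 on chromosome 19, and 26 and 21 elsewhere. From replicates 2 and 3 alone they were 56 and 14, and 21 and 18. Camera with an estimated correlation gave p = 0.218 and 0.831 for these 2 parts.

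With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 423, 289, 803 and 1005 genes for TNFα in control cells, TNFα in knock-down cells, knock-down without TNFα and knock-down with it, and the highest of the other splits 1, 0, 1 and 0, so in each case 1 of the 10 reached the real count. For the interaction, 26 of 40 splits gave as many genes at an unadjusted p under 0.05 as the real 184, up to 3662, which points to a structure of the samples, since the difference between the lines enters the interaction when lines are exchanged.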
